A study of Mus musculus with 15 samples.

How the data were processed

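Total RNA of RAW264.7 mouse macrophages was measured on 15 arrays, 3 in each of 5 groups: no LPS with vehicle, and LPS with vehicle, with 13-HDHEA, with 16-HDHEA or with both compounds. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, biotin-labelled target was made from total RNA with an Affymetrix whole-transcript sense assay, and RNA was used only where it was intact on a bioanalyzer. The deposited values are log2 expression per probe set, and per the submitters' processing notes they were made with RMA, which corrects background, quantile-normalizes the arrays and summarises probes. Its version and the chip definition are not given in the sources used here. Quantile normalization gives every array nearly the same distribution, so a shift shared by most genes cannot be seen, and RMA compresses changes of dim probe sets. The values ran from 0.473 to 13.36, and array medians from 3.62 to 3.69. No detection p-values were used here, so that a dim probe set was judged only by its rank on the array.

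Of 41345 probe sets, the platform's gene table listed 25335, of which 23521 had 1 gene symbol and 1814 several, and it did not list 16010. Of those with 1 symbol, 23328 were found by gene identifier in the RefSeq table of GRCm38.p6, and no symbol needed to be updated. For the 1082 genes with several probe sets, the one with the highest mean over all arrays was kept, which left 22180 genes. A gene was tested where its value exceeded the array's own 40th percentile over all probe sets (3.16 to 3.22) in at least 3 arrays. This left 15468 genes and set aside 6712. Where the dimmer group of a named gene lay below the mean of its arrays' 40th percentiles, the fold is given as a lower bound, from that percentile to the brighter group, a choice made after the values were seen.

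Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) on 1 model of group means over all 15 arrays, which leaves 10 residual degrees of freedom and a prior of 3.59. The comparisons were LPS against no LPS, each HDHEA treatment against vehicle, 13-HDHEA against 16-HDHEA, the combined treatment against the mean of the single ones, and the mean of all HDHEA treatments against vehicle. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with calls at an adjusted p under 0.05. Intervals are 95% intervals of the log2 difference from the same fit. Differences are given as the first group minus the second.

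28 gene lists were fixed before the data were examined, as were the groups, the design, the other settings to be tried and the rule for named genes. They cover pro-inflammatory cytokines, chemokines, anti-inflammatory and feedback genes, NF-kB targets, interferon-stimulated genes, nitric oxide and host defence genes, eicosanoid enzymes, N-acyl ethanolamine and endocannabinoid genes, NRF2, PPAR and LXR targets, cholesterol and fatty acid synthesis, glycolysis, respiration, cell cycle, stress response, antigen presentation, alternative activation, lysosome, inflammasome, apoptosis and p53 targets, macrophage identity, osteoclast markers, and markers of fibroblasts, lymphocytes, neutrophils, and epithelial and endothelial cells. Of their 616 symbols, 568 had a probe set and 517 were tested. Some genes belong to more than 1 list. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives.

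Genes were named by 3 parts of a rule: up to 10 genes a direction with the largest change among those called with the same sign in each experiment, leaving out predicted and RNA genes; up to 4 members of each list with the smallest p; and always Tnf, Il1b, Il6, Il10, Il1rn, Nos2, Ptgs2, Ccl2, Hmox1 and Cnr2. Mnd1 is named under the first part, and its values in the other comparisons, and the interferon-stimulated and other genes set beside their values in another comparison, were added after those values were seen.

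The labels give each replicate number its own experiment identifier, so arrays with the same number share an experiment, and the replicates are separate experiments. Deviations from group means correlated between 0.084 and 0.4 over the 30 same-numbered pairs, above 0.1 in 28 of them, and each of the 15 arrays correlated best with its own number. The fit with experiment as a block has 8 residual degrees of freedom. Intervals and p-values come from the fit without the block unless stated, and so leave this pairing out. For 13-HDHEA against vehicle the median SE over genes was 0.126 without the block and 0.109 with it.

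Effects that share the vehicle arrays were set against 1000 simulated sets of unchanged groups, and against values from different experiments, the latter chosen after the data were seen. Each simulated array, vehicle included, was what the fit with experiment as a block left over on an array, shuffled and given a random sign. The model was tested on simulated data for 13-HDHEA against vehicle, with 200 of 15468 genes changed in each of 10 simulations. It recovered 37% of genes changed 1.41-fold, 89.3% of those changed 2-fold and 99.7% of those changed 4-fold, with 1.57% of its calls false. With experiment as a block it recovered 57.5%, 95.8% and 100%, with 4.94% false. The simulated noise was independent between genes. On the arrays genes varied together (estimated correlation 0.416 for the interferon-stimulated genes), so these shares may not hold for them. Alternatives were experiment as a block, only the groups compared in the fit, eBayes with trend and robust settings, array weights, arrays centred on their median, repeated quantile normalization, no filter or one at the 60th percentile, the mean of a gene's probe sets, each array left out in turn, and other thresholds. Figures were drawn with matplotlib 3.10.9. Probe sets of several genes or without a listed gene were left out of the comparisons because they name no single gene, and no coordinates are given because no build is named for the array.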

Results

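Gene expression was measured in RAW264.7 cells, a mouse macrophage line, that were activated with lipopolysaccharide (LPS) and exposed to hydroxylated docosahexaenoyl ethanolamides (HDHEAs). LPS is a component of the outer membrane of Gram-negative bacteria that macrophages sense through a Toll-like receptor. HDHEAs are derivatives of the fatty acid docosahexaenoic acid, joined to ethanolamine and carrying a hydroxyl group. 13-HDHEA and 16-HDHEA are positional isomers, which differ in the carbon that carries this group. 15 arrays fell into 5 groups of 3. Cells without LPS received vehicle (0.1% ethanol), and the other groups received 1.0 µg/mL LPS after 30 min with vehicle, with 5.0 µM 13-HDHEA, with 5.0 µM 16-HDHEA, or with 2.5 µM of each compound (the combined treatment). RNA was taken after 24 h, and each replicate number is 1 of 3 experiments with its own identifier in the labels. The number of arrays, 3 a group, limits the precision of each value.

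The deposited values covered 41345 probe sets on a log2 scale, and 15468 genes were tested. Array medians over all probe sets lay between 3.62 and 3.69. The first principal component held 63.8% of the variance between arrays and separated the 3 arrays without LPS from the 12 with it, while the second held 6.73%.

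The first comparison asked what LPS alone did to these cells, with vehicle on both sides. Cytokine and acute-phase transcripts were among those that rose most. Il1a and Il1b, which encode interleukin-1 cytokines, rose at least 473.8-fold and 486-fold: Il1a went from 3.08 ± 0.0441 (SD, n = 3) to 12.05 ± 0.078 on the log2 scale, and Il1b from 3.42 ± 0.139 to 12.34 ± 0.0457. The acute-phase gene Saa3 rose 457-fold and the cytokine gene Il6 at least 200.9-fold, from 2.56 ± 0.246 to 10.82 ± 0.0515. Without LPS, Il1a and Il6 lay below the 40th percentile of all 3 arrays, and their folds are lower bounds taken against it. Il1b without LPS lay just above it, at percentile 45.6 on average, so its fold also rests on a level near background. Among the genes that fell most, Cxcr4, the receptor of the chemokine Cxcl12, was 8.81-fold lower, and Alox5, the lipoxygenase that starts leukotriene synthesis, was 5.74-fold lower.

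The 10 largest measured increases that went the same way in each experiment also included Lcn2, a lipocalin that binds bacterial siderophores (log2 change 7.17), the plasminogen activator inhibitor Serpinb2 (at least 6.39), Acod1, which makes itaconate (6.20), the granulocyte growth factor gene Csf3 (at least 5.95, SE of the measured change 0.54), the chemokine gene Ccl5 (5.72) and the scavenger receptor gene Marco (5.67). Their adjusted p ran from 1.91e-17 to 1.18e-06 in limma. The 10 largest decreases were those of the p38 kinase activator Map2k6 (-3.14), Cxcr4 (-3.14), the Ras exchange factor gene Rasgrp3 (-3.06), the mitotic cyclin gene Ccnb2 (-2.84), the cyclin-dependent kinase inhibitor gene Cdkn2c (-2.84), the matrix protein gene Tgfbi (-2.73), Cd300lg (-2.63), the spindle gene Aspm (-2.59), Alox5 (-2.52) and the linker histone gene H1f5 (-2.48), with adjusted p up to 2.54e-05. In all, 4616 genes passed, 2089 higher and 2527 lower with LPS. Of these, 498 higher and 519 lower genes changed at least 2-fold.

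**Figure D1:**
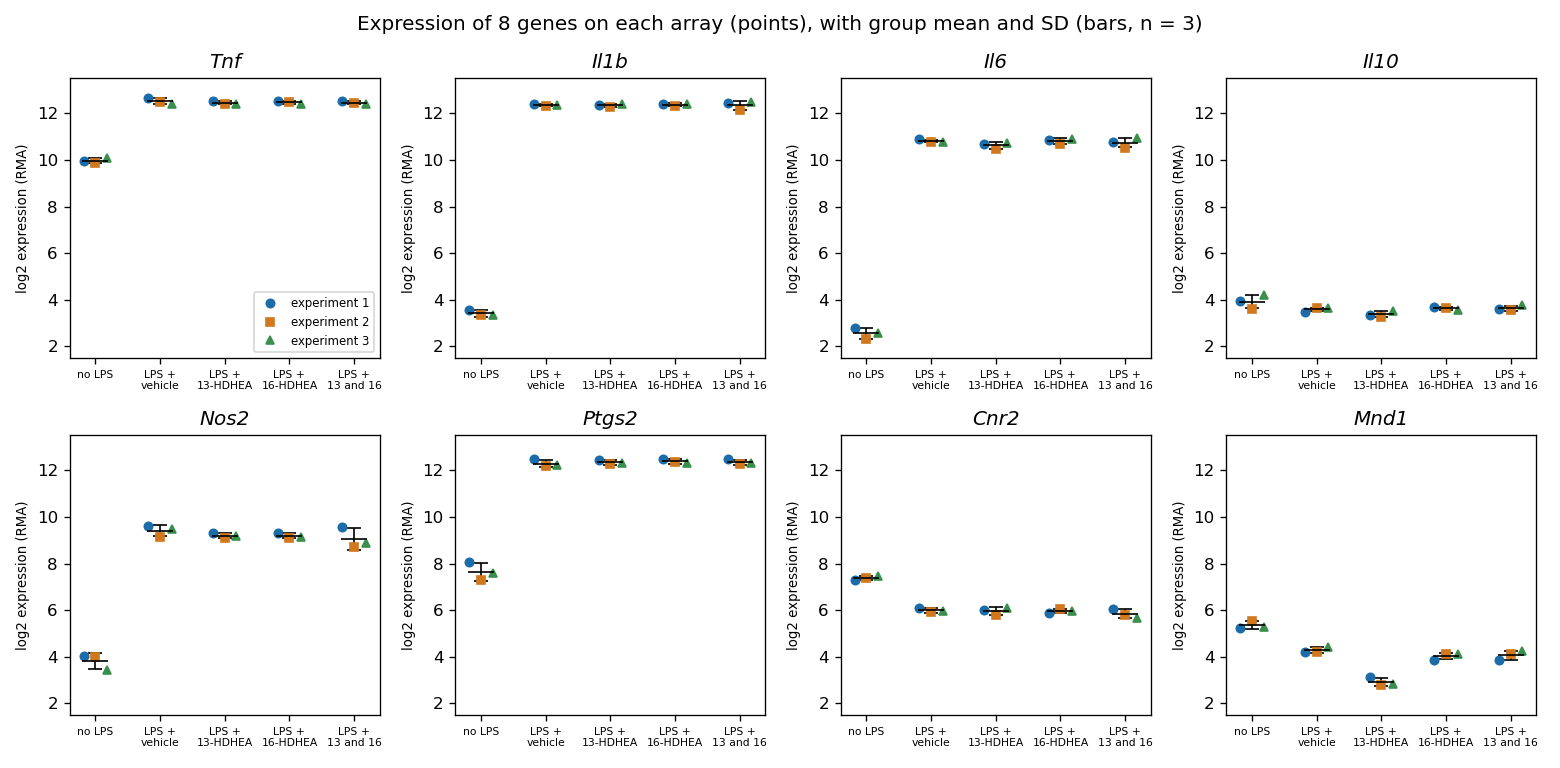
Expression on the log2 scale (RMA) of 8 genes in each of the 5 groups, with 1 point per array coloured by experiment and bars for the mean and SD of 3 arrays. LPS moved Tnf, Il1b, Il6, Nos2 and Ptgs2 upward and Cnr2 downward, while Mnd1 was lowest with 13-HDHEA, at 2.92 and below the arrays' 40th percentile, against 4.28 with vehicle.

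Of the pro-inflammatory cytokine genes, 15 of 18 rose with LPS, none fell and 3 did not pass (16 rose when adjusted over the list alone). Their median log2 change was 2.68, and Tnf rose by 2.55, from an already high 9.96 ± 0.111 (SD, n = 3). Of 20 chemokine genes, 14 rose and 1 fell, the same counts when adjusted over the list alone, with Ccl7 at 4.83, Cxcl10 at 4.47 and Ccl2, the monocyte attractant, at 2.01. Targets of the transcription factor NF-kB rose in 20 of 21 cases, with Nfkbiz at 3.64 and the mitochondrial superoxide dismutase gene Sod2 at 2.17. The remaining NF-kB gene did not pass over all genes, but fell when adjusted over the list alone and with experiment as a block (1 gene). Interferon-stimulated genes rose in 31 of 32 cases, over all genes and adjusted over the list alone, with Oasl1 at 3.71, the nucleic acid sensor gene Zbp1 at 3.64 and the interferon regulator gene Irf7 at 2.80. Of 21 genes for nitric oxide, oxidants and host defence, 17 rose and 1 fell (18 and 1 adjusted over the list alone), among them Nos2, the inducible nitric oxide synthase, at 5.59 and the arginine transporter gene Slc7a2 at 3.45.

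Genes that restrain inflammation rose as well. Of 19 anti-inflammatory and feedback genes, 13 rose and 1 fell (15 and 2 adjusted over the list alone), with Socs3, an inhibitor of cytokine receptors, at 4.88, the ribonuclease gene Zc3h12a at 3.16, the kinase gene Irak3 at 2.49 and the interleukin-1 receptor antagonist gene Il1rn at 1.90. Il10, a cytokine that restrains macrophages, was low in both groups, at 3.58 ± 0.0829 with LPS and 3.92 ± 0.289 without (SD, n = 3), and differed by -0.33 (adjusted p = 0.06 in limma). It passed with experiment as a block (adjusted p = 0.0389) and without the replicate 2 array that had no LPS (adjusted p = 0.00441), and it was lower with LPS in 2 of 3 experiments. The antigen presentation and costimulation genes rose in 17 of 20 cases (18 rose and 1 fell adjusted over the list alone), with the checkpoint ligand gene Cd274 at 3.64 and the costimulatory genes Cd80 and Cd40 at 3.32 and 3.31. Of 20 inflammasome and pyroptosis genes, 10 rose and 4 fell, over all genes and adjusted over the list alone, with Nlrp3, the sensor of an inflammasome, at 2.02 and the kinase gene Nek7 at -0.89. These 8 lists shifted upward in camera with adjusted p from 1.04e-27 to 0.00349, and each also passed with an estimated correlation, where the highest adjusted p was 0.0217.

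All 31 tested cell cycle and DNA replication genes fell, over all genes and adjusted over the list alone, with a median of -1.58. Cyclin D1 (Ccnd1) stood at -1.95, the proliferation marker Mki67 at -1.87 and the replication helicase genes Mcm5 and Mcm2 at -1.62 and -1.49. Camera gave this list an adjusted p of 8.65e-24, and adjusted p = 0.0658 with an estimated correlation. Cholesterol biosynthesis and uptake genes fell in 17 of 21 cases and rose in 1, over all genes and adjusted over the list alone, with Dhcr7, which catalyses the last step of cholesterol synthesis, at -0.70 and Sqle at -0.60. The camera adjusted p was 1.96e-06, and adjusted p = 0.191 with an estimated correlation. Of 26 genes of the unfolded protein and integrated stress response, 15 rose and none fell (16 adjusted over the list alone, and 2 fell with experiment as a block), with Nupr1 at 1.27 and the chaperone gene Dnajb9 at 1.21. Camera gave 1.98e-05, and adjusted p = 0.143 with an estimated correlation. NRF2 antioxidant genes rose in 11 of 22 cases and fell in 4 (13 and 4 adjusted over the list alone), with the cystine transporter gene Slc7a11 at 3.59, the heme oxygenase gene Hmox1 at 0.78 and the glutathione synthesis gene Gclc at -0.72. Camera gave 0.00407, and adjusted p = 0.22 with an estimated correlation. Glycolysis and hypoxia-linked genes rose in 7 of 19 cases and none fell, the same when adjusted over the list alone (1 fell there with experiment as a block), with hexokinase 2 (Hk2) at 1.47. Their shift passed camera narrowly at 0.0443, with adjusted p = 0.498 with an estimated correlation. It was lost without the replicate 1 vehicle array (adjusted p = 0.0899), the replicate 2 vehicle array (0.0642) or the replicate 3 array without LPS (0.119), and also with only the groups compared in the fit (0.0556), repeated quantile normalization (0.0576) or the 60th percentile filter (0.0577).

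Lipid mediator genes moved in both directions, and none of their lists shifted in camera. Of 20 eicosanoid and oxylipin genes, 6 rose and 7 fell, over all genes and adjusted over the list alone, with a camera adjusted p of 0.53. Ptgs2, the inducible cyclooxygenase, stood at 4.64 and the prostaglandin E receptor gene Ptger2 at 2.51, against Alox5 at -2.52. Of 21 N-acyl ethanolamine and endocannabinoid genes, 4 rose and 6 fell, again with the same counts when adjusted over the list alone (adjusted p = 0.668, median 0.02, mean -0.04). In this list Gpr18, an orphan receptor proposed to bind cannabinoid-like lipids, rose by 3.32, while the cannabinoid receptor gene Cnr2 fell by 1.38 and the diacylglycerol lipase gene Daglb fell by 1.41. PPAR targets and fatty acid oxidation genes rose in 3 and fell in 8 of 21 cases (4 and 8 adjusted over the list alone), with lipoprotein lipase (Lpl) at -1.15, Angptl4 at -1.13 and the nuclear receptor gene Ppard at 1.46 (list adjusted p = 0.178). Fatty acid synthesis and desaturation genes rose in 2 and fell in 9 of 19 cases (3 and 9 adjusted over the list alone), with the triglyceride synthesis gene Dgat2 at 2.87 and fatty acid synthase (Fasn) at -0.78 (list adjusted p = 0.061). That list passed, downward, without the replicate 3 array that had no LPS (0.038) or the replicate 3 vehicle array (0.0314). Of 10 LXR targets, 4 rose and 2 fell, the same when adjusted over the list alone, with the cholesterol exporter gene Abca1 at 0.91 (list adjusted p = 0.355). Of 23 respiration and TCA cycle genes, 5 fell and none rose, the same when adjusted over the list alone, with the isocitrate dehydrogenase gene Idh2 at -0.68 (list adjusted p = 0.0973). These list values are from camera. In fry the eicosanoid (adjusted p = 0.000157), PPAR (0.000724), LXR (0.00168), fatty acid synthesis (0.00047) and respiration (0.000249) lists passed. The N-acyl ethanolamine list did not (0.129).

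Of 20 macrophage identity genes, 5 rose and 4 fell (6 and 4 adjusted over the list alone), with the macrophage surface marker gene Adgre1 at 4.50 and the fractalkine receptor gene Cx3cr1 at -2.43 (adjusted p = 0.668, median -0.10, mean 0.21). Alternative activation markers rose in 4 and fell in 4 of 16 cases, with the chemokine gene Ccl22 at 4.09 and the beta-glucan receptor gene Clec7a at -2.05 (adjusted p = 0.947, median -0.08, mean 0.24). Osteoclast markers rose in 3 and fell in 4 of 13 cases, with the gelatinase gene Mmp9 at 3.23 (adjusted p = 0.809, median -0.02, mean 0.20). For both of these lists the counts were the same when adjusted over the list alone. Of 24 lysosome and autophagy genes, 7 rose and 7 fell (7 and 9 adjusted over the list alone), with the acid lipase gene Lipa at -0.66 (adjusted p = 0.742). Of 19 apoptosis and p53 genes, 5 rose and 3 fell (5 and 5 adjusted over the list alone, and also over all genes with experiment as a block), with the death receptor gene Fas at 1.94 and Sesn1 at -1.04 (adjusted p = 0.668). In fry the macrophage identity (adjusted p = 0.000839) and osteoclast (0.0135) lists passed. The alternative activation (0.0908) and lysosome (0.194) lists did not.

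Markers of other cell types did not shift as lists. Of 7 neutrophil markers, 2 rose, the same when adjusted over the list alone: S100a8 (1.30) and Mmp8 (at least 1.06, its level without LPS being below the 40th percentile), the latter not without the replicate 1 vehicle array (adjusted p = 0.0585) or the replicate 2 array without LPS (0.053). None of 6 lymphocyte markers passed, over all genes or adjusted over the list alone. Of 10 fibroblast markers, Pdgfra passed over all genes (0.96, adjusted p = 0.0472) but none did when adjusted over the list alone. Its call was lost without the replicate 1 or replicate 2 array of the group without LPS (0.104 and 0.19) or of the vehicle group (0.127 and 0.14), and Fap joined it with experiment as a block (adjusted p = 0.0464, 0.116 without the block). Of 11 epithelial and endothelial markers, Vwf fell by 0.49 and Cdh5 rose by 0.42, and 1 fell and none rose when adjusted over the list alone. The Vwf call was lost without the replicate 2 array that had no LPS (0.0512) or the replicate 3 vehicle array (0.0685). The Cdh5 call was lost without any 1 of 5 arrays: vehicle replicates 1, 2 and 3 (0.113, 0.0664 and 0.088) and, of the cells without LPS, replicates 2 and 3 (0.101 and 0.174). Camera gave these lists adjusted p of 0.643 (neutrophil), 0.742 (lymphocyte), 0.466 (fibroblast) and 0.98 (epithelial and endothelial).

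The LPS calls were spread almost evenly between directions, and which direction held more genes depended on the scaling: with each array centred on its median over the tested genes, 2534 genes were higher and 2082 lower.

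**Figure D2:**
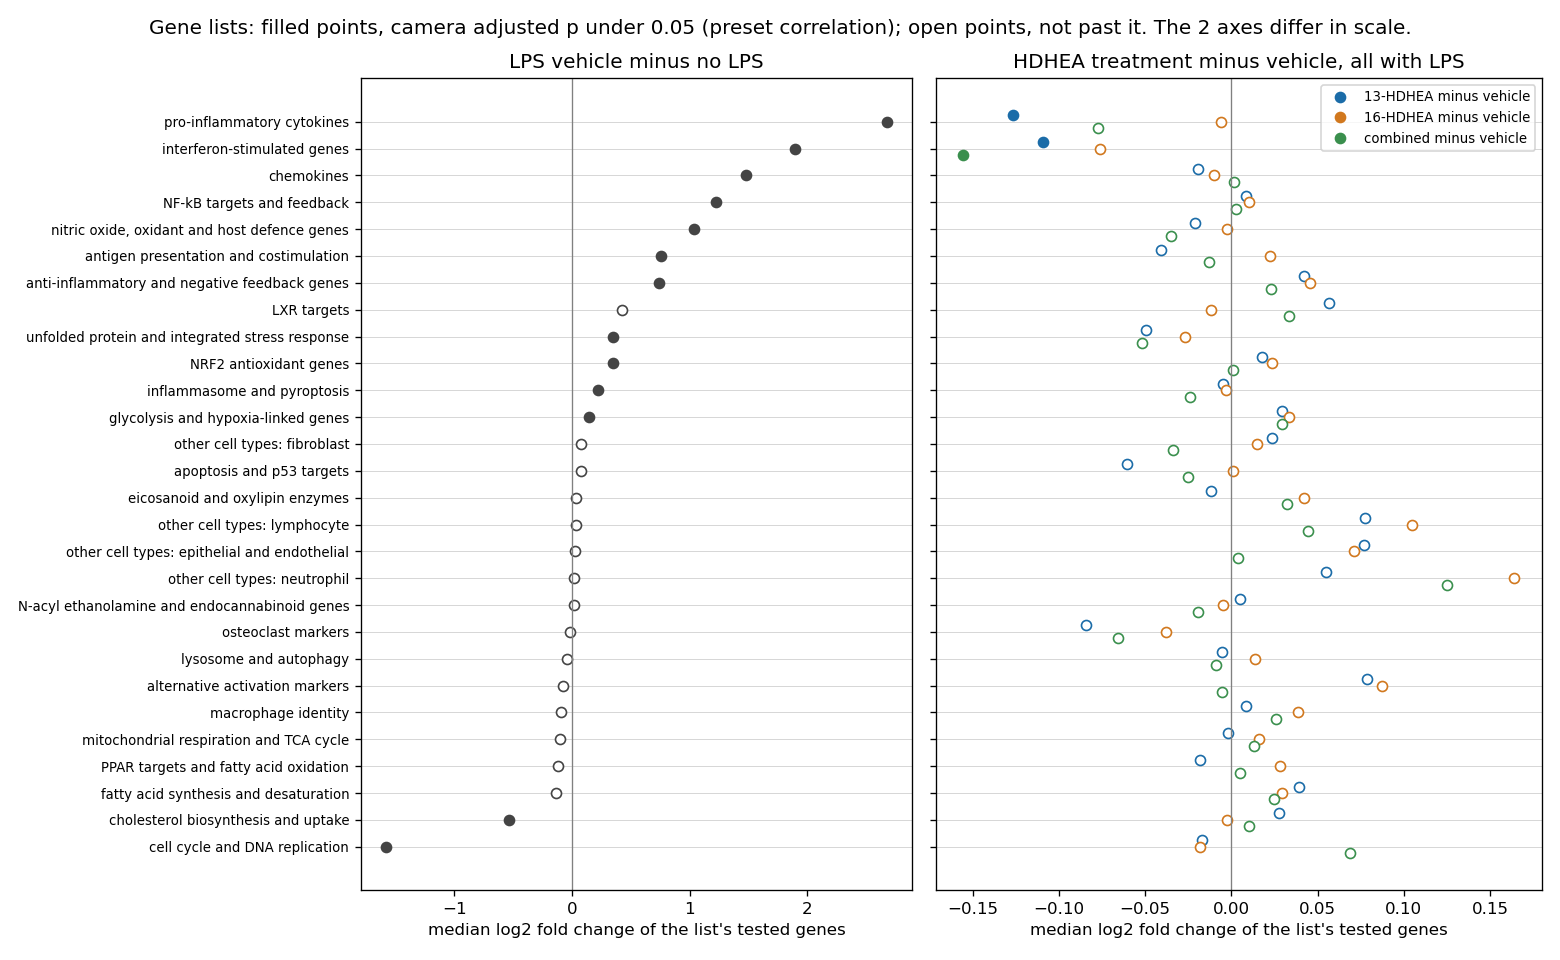
Median log2 fold change of the tested genes of each of 28 gene lists, for LPS against no LPS (left) and for each HDHEA treatment against vehicle (right), on axes of different scale. Filled points passed camera with its preset correlation at an adjusted p under 0.05, which 13 lists did for LPS and 3 points did among the HDHEA comparisons.

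The second comparison asked whether 5.0 µM 13-HDHEA changed expression in LPS-activated cells. 1 gene changed, Mnd1 (Entrez gene 76915, probe set 17406323), which encodes a partner of the recombinases that pair homologous chromosomes in meiosis. It was at least 2.10-fold lower with 13-HDHEA, at 2.92 ± 0.183 (SD, n = 3) against 4.28 ± 0.128 with vehicle, where cells without LPS had 5.35 ± 0.167. The log2 change as measured was -1.35 (SE 0.127, 95% interval -1.63 to -1.08, adjusted p = 0.00091 in limma), and it was -1.06, -1.43 and -1.57 in the 3 experiments. With 13-HDHEA the probe set lay below the 40th percentile of all 3 arrays (at percentile 33 on average), so that the fold is a lower bound taken against it and the size of the change was not resolved. The call was lost when the fit held only the arrays of these groups (adjusted p = 0.105), and without vehicle replicate 1 a count of 2 genes passed.

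The inflammatory genes fixed in advance did not pass with 13-HDHEA. Tnf differed by -0.07 (95% interval -0.25 to 0.12), Il6 by -0.19 (-0.47 to 0.09), Il1b by 0.01 (-0.21 to 0.22), Nos2 by -0.21 (-0.66 to 0.23) and Il10 by -0.20 (-0.47 to 0.07). Ptgs2, Ccl2, Hmox1, Cnr2 and Il1rn lay between -0.14 and 0.05, and each of these 10 genes had an adjusted p of 1. Interferon-stimulated genes nevertheless passed camera as a list, but only with its preset correlation. 30 of 32 were lower with 13-HDHEA, with a median of -0.11, and Ifit1 stood at -0.46, Cmpk2 at -0.39, Ifit2 at -0.36 and Rsad2 at -0.35. None of the 32 passed alone, over all genes or adjusted over the list alone (3 did so over the list alone with experiment as a block). The mean of the list was -0.118, -0.23 and -0.113 in the 3 experiments. Camera gave an adjusted p of 0.0049 with its preset correlation of 0.01. With the estimated correlation, 0.416 for this list, it gave an adjusted p of 0.803, and fry gave 0.934. The camera call was lost without vehicle replicate 2 (0.249), vehicle replicate 3 (0.101) or 13-HDHEA replicate 1 (0.232).

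Pro-inflammatory cytokine genes were lower in 15 of 18 cases, with a median of -0.13. None passed alone, over all genes or adjusted over the list alone, and the macrophage growth factor gene Csf1 stood at -0.36 and Tnfsf15 at -0.33. Camera gave an adjusted p of 0.0355, and adjusted p = 0.776 with an estimated correlation. The shift was lost without vehicle replicate 1 (0.166) or 2 (0.0654), without 13-HDHEA replicate 2 (0.291) or 3 (0.0546), and with a filter at the 60th percentile (0.0524). No other list passed. The unfolded protein and stress response genes were lower in 22 of 26 cases (adjusted p = 0.0833), and passed without 13-HDHEA replicate 2 (0.01) or vehicle replicate 3 (0.0213), while the alternative activation markers (higher in 11 of 16 cases, adjusted p = 0.088) passed without 13-HDHEA replicate 2 (0.0233). A few members passed only when adjusted over the list alone: the leukotriene C synthase gene Ltc4s (0.49, 1 of 20 eicosanoid genes, 2 with experiment as a block), the fibronectin gene Fn1 (0.32, 1 of 16 alternative activation markers) and the proteoglycan gene Dcn (0.34, 1 of 10 fibroblast markers). Of the PPAR targets, none did so without the block and 3 did with it. The lipid droplet gene Plin2 stood at 0.36 and the carnitine transferase gene Cpt1a at 0.35. The level of Dcn with vehicle was 3.20, just above those arrays' 40th percentile (3.163 to 3.175), so its change rests on a level near background. That of Fn1 with vehicle was 3.45, also near background. Over all genes, 660 had an unadjusted p under 0.05 in limma and 963 with experiment as a block, on either side of the 773.4 expected with no effect.

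The third comparison asked the same of 5.0 µM 16-HDHEA. No gene passed in limma. 460 genes had an unadjusted p under 0.05 (686 with experiment as a block), the smallest adjusted p was 0.683, and the fit with experiment as a block also called 0. Tnf differed from vehicle by -0.04 (95% interval -0.23 to 0.14), Il6 by -0.01 (-0.29 to 0.27), Il1b by 0.03 (-0.18 to 0.25), Nos2 by -0.22 (-0.66 to 0.23) and Ptgs2 by 0.09 (-0.24 to 0.42). Mnd1 stood at 4.03 ± 0.131 (SD, n = 3), a difference of -0.25 that did not pass (adjusted p = 1 in limma). Klf4, a transcription factor gene of the alternative activation list, had the largest difference among the named genes (0.59). Ltc4s (0.33) and the MHC class II activator gene Ciita (0.32) were higher as well, and none of these passed. Ciita was dim with vehicle (3.71).

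No list shifted with 16-HDHEA. Camera gave 4 lists an unadjusted p under 0.05, and fry and camera with an estimated correlation called 0 at the adjusted threshold. Interferon-stimulated genes were lower in 26 of 32 cases, with a median of -0.08, Ifit1 at -0.29 and Rsad2 at -0.28, and an adjusted p of 0.32. With experiment as a block this list passed (adjusted p = 0.0169, and adjusted p = 0.85 with an estimated correlation). It also passed without vehicle replicate 1 (0.000885), 16-HDHEA replicate 2 (0.021) or 16-HDHEA replicate 3 (0.0173). The neutrophil markers were higher in 7 of 7 cases and the alternative activation markers in 10 of 16, each with an adjusted p of 0.32, and the cell cycle genes (lower in 17 of 31 cases, adjusted p = 0.875) passed without vehicle replicate 1 (0.0217). No member of any list passed when adjusted over the list alone.

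The fourth comparison asked what 2.5 µM of each compound did together. No gene passed in limma. 539 genes had an unadjusted p under 0.05 (791 with experiment as a block), the smallest adjusted p was 1, and the fit with experiment as a block also called 0. Tnf differed from vehicle by -0.05 (95% interval -0.24 to 0.13), Il6 by -0.07 (-0.36 to 0.21), Il1b by 0.01 (-0.21 to 0.22) and Nos2 by -0.35 (-0.80 to 0.09). Mnd1 stood at 4.07 ± 0.188 (SD, n = 3), a difference of -0.21 (adjusted p = 1 in limma). Alox5 (0.45), Ltc4s (0.32), the arginase gene Arg1 (0.31) and Plin2 (0.31) were higher, and none passed. The level of Arg1 with vehicle was 3.24, just above those arrays' 40th percentile, so its change rests on a level near background.

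Interferon-stimulated genes were lower in 29 of 32 cases with the combined treatment, with a median of -0.16, Ifit1 at -0.50 and the antiviral GTPase gene Mx1 at -0.46. None passed alone, over all genes or adjusted over the list alone (4 did so over the list alone with experiment as a block). Camera gave an adjusted p of 8.54e-05, and adjusted p = 0.916 with an estimated correlation. The shift was lost without replicate 1 of the combined treatment (0.249) or vehicle replicate 2 (0.0804). Pro-inflammatory cytokine genes were lower in 13 of 18 cases (adjusted p = 0.182), and passed without replicate 1 of the combined treatment (0.0339). The cell cycle genes were higher in 22 of 31 cases (adjusted p = 0.303), and passed without that same array (1.49e-07) or without vehicle replicate 3 (0.0238). With the estimated correlation, 0.588 for this list, camera gave an adjusted p of 0.986 on all arrays. The unfolded protein and stress response genes were lower in 17 of 26 cases (adjusted p = 0.303), and passed without vehicle replicate 3 (0.0266). 1 PPAR target passed when adjusted over the list alone with experiment as a block, and none without it.

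**Figure D3:**
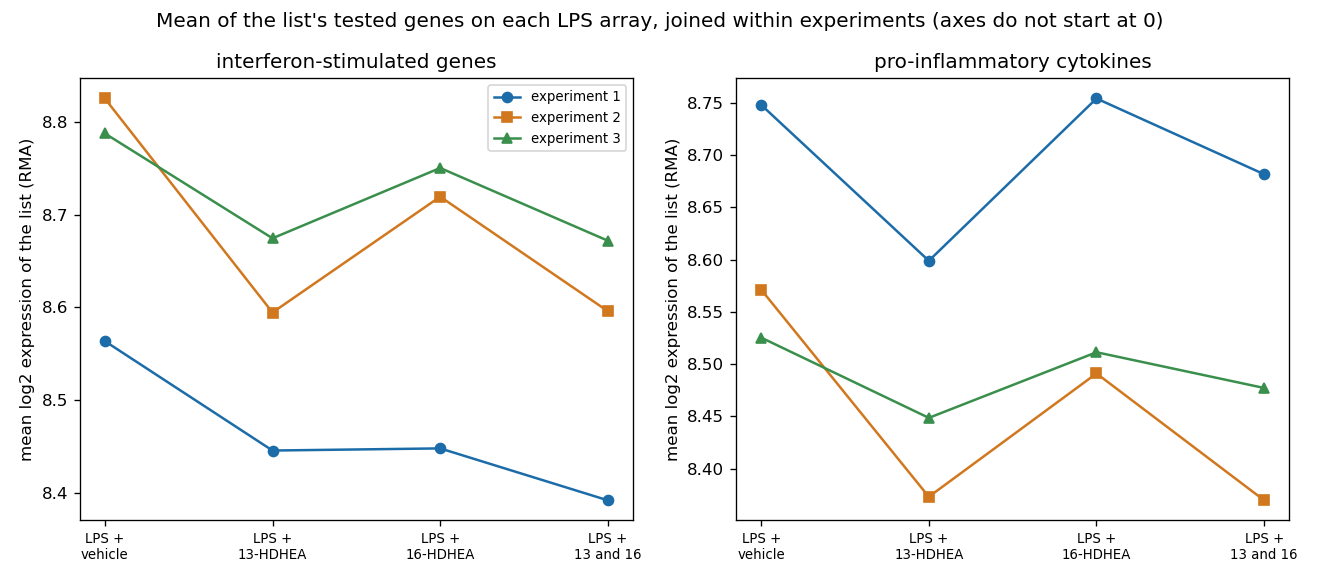
Mean log2 expression of the tested interferon-stimulated genes (left) and pro-inflammatory cytokine genes (right) on each array with LPS, with lines joining the 4 arrays of an experiment. The interferon mean lay below the vehicle array of its own experiment in 9 of 9 arrays with an HDHEA, and the cytokine mean in 8 of 9.

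The isomers were then compared directly at the matched dose of 5.0 µM. Mnd1 was at least 1.77-fold lower with 13-HDHEA than with 16-HDHEA, again a lower bound because the 13-HDHEA arrays lay below their 40th percentile. The log2 difference as measured was -1.11 (95% interval -1.38 to -0.83, adjusted p = 0.0102 in limma), with -0.75, -1.32 and -1.25 in the 3 experiments. It was the 1 gene that passed. The call was lost without 13-HDHEA replicate 2 (0.086) or 3 (0.108), without 16-HDHEA replicate 2 (0.112) or 3 (0.109), and with only the arrays of these groups in the fit (0.241). The difference itself stayed between -1.04 and -1.07 without each of these arrays, and at -1.11 in the smaller fit. No difference passed for the inflammatory genes, and the intervals bound its size as measured on the arrays. It was -0.02 for Tnf (95% interval -0.21 to 0.16), -0.03 for Il1b (-0.24 to 0.19), -0.18 for Il6 (-0.46 to 0.10), -0.25 for Il10 (-0.51 to 0.02), 0.01 for Nos2 (-0.44 to 0.45) and -0.04 for Ptgs2 (-0.37 to 0.28). The lysophosphatidylinositol receptor gene Gpr55 (0.46, interval 0.15 to 0.78), the haptoglobin gene Hp (0.45, 0.15 to 0.76) and Dcn (0.31) did not pass over all genes. Dcn, which was dim with vehicle (3.20), was 1 of 10 fibroblast markers past the threshold adjusted over the list alone. Gpr55 was also dim with vehicle (3.57). For 98.9% of the genes the interval of the difference lay within 2-fold either way, and for 87% within 1.5-fold.

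No list differed between the isomers in camera. 1 list had an unadjusted p under 0.05, and fry and camera with an estimated correlation called 0. That list was the pro-inflammatory cytokine genes, lower with 13-HDHEA in 16 of 18 cases with a mean of -0.112 (adjusted p = 0.615). With experiment as a block it passed (adjusted p = 0.0271, and adjusted p = 0.382 with an estimated correlation). Interferon-stimulated genes were lower with 13-HDHEA in 25 of 32 cases (adjusted p = 0.807), and passed without 16-HDHEA replicate 1 (0.00157). Without that array the cell cycle genes passed as well, in the opposite direction to the test on all arrays (0.0473 against 0.991, where their median was -0.00329 and their mean 0.00305).

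The combined treatment was also set against the mean of the single treatments, which it matched in total dose. No gene passed in limma. 496 genes had an unadjusted p under 0.05 (673 with experiment as a block), the smallest adjusted p was 1, and the fit with experiment as a block called 0. The apolipoprotein genes Apoe and Apoc2 were higher by 0.31 and 0.18 with the combination and did not pass, nor did Mnd1, whose 13-HDHEA arrays lay below their 40th percentile. Tnf differed by 0.00 (95% interval -0.15 to 0.16) and Il6 by 0.03 (-0.22 to 0.27). No list passed in camera, where 1 had an unadjusted p under 0.05, and fry and camera with an estimated correlation called 0. Cell cycle genes were higher in 26 of 31 cases with a mean of 0.0722 (adjusted p = 0.285), and passed with experiment as a block (adjusted p = 0.032, and adjusted p = 0.958 with an estimated correlation). They also passed without replicate 1 of the combined treatment (8.13e-10), 13-HDHEA replicate 2 (0.0301), 16-HDHEA replicate 2 (0.0482) or 16-HDHEA replicate 3 (0.00332), and the interferon-stimulated genes passed without 16-HDHEA replicate 1 (0.0233). A count of 2 LXR targets passed when adjusted over the list alone with experiment as a block, and none without it.

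Averaged over the 3 HDHEA treatments, 9 arrays against 3, no gene differed from vehicle in limma. 586 genes had an unadjusted p under 0.05 (885 with experiment as a block), the smallest adjusted p was 0.4, and the fit with experiment as a block called 0. Tnf differed by -0.05 (95% interval -0.20 to 0.10), Il6 by -0.09 (-0.32 to 0.14), Il1b by 0.01 (-0.16 to 0.19) and Nos2 by -0.26 (-0.63 to 0.10). Interferon-stimulated genes were lower in 28 of 32 cases with a mean of -0.137, and their camera adjusted p was 0.000398, with adjusted p = 0.769 with an estimated correlation. This shift was lost without vehicle replicate 2 (0.187) or 3 (0.0614). An exact permutation of which LPS array of each experiment was the vehicle array was added after the data were seen. There the two-sided p of this list was 0.0156, the smallest that 64 arrangements allow, and 0.146 after adjustment over the 28 lists. Unless many lists reached that smallest p together, none could pass after adjustment. Pro-inflammatory cytokine genes were lower in 14 of 18 cases (adjusted p = 0.0909), and passed with experiment as a block (adjusted p = 0.0483, and adjusted p = 0.444 with an estimated correlation) or without replicate 1 of the combined treatment (0.0443). The unfolded protein and stress response genes were lower in 21 of 26 cases (adjusted p = 0.0909), and passed without 13-HDHEA replicate 2 (0.0485), 16-HDHEA replicate 2 (0.0458) or vehicle replicate 3 (0.0153). No member of any list passed when adjusted over the list alone. With experiment as a block, 3 interferon-stimulated genes, 3 eicosanoid genes and 3 PPAR targets did.

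The resemblance of the HDHEA effects could not be told apart from that produced by shared vehicle arrays. Across genes, which are not independent replicates, the log2 changes correlated at 0.542 between 13-HDHEA and 16-HDHEA, at 0.529 between 13-HDHEA and the combination, and at 0.548 between 16-HDHEA and the combination. Simulated unchanged groups that shared a simulated vehicle group gave means of 0.484, 0.488 and 0.475. Their central 95% ran from -0.025 to 0.825, -0.0326 to 0.819 and -0.0464 to 0.815, too wide to exclude a shared effect. The covariances were 0.0112, 0.0114 and 0.0109, against 0.0102, 0.0103 and 0.0101 in the simulations. Taken from different experiments, which share no array, the correlations averaged 0.0229, 0.0205 and 0.000146. Each effect was there a difference of single arrays, whose noise lowers a correlation. No gene was called in any pair of these comparisons.

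Whether the HDHEAs opposed LPS was asked over the 4616 genes that LPS changed. Across these genes the effect of 13-HDHEA correlated with that of LPS at -0.183 and that of 16-HDHEA at -0.0894. Both lay inside the central 95% of simulated unchanged groups, which share a simulated vehicle group (-0.209 to 0.113 and -0.208 to 0.0994). The combined treatment gave -0.27, below the simulated -0.21 to 0.0988, with a covariance of -0.0365 against a simulated mean of -0.00675. When genes and LPS effects came from 2 experiments and the HDHEA effect from the remaining one, the correlation averaged -0.0498 for 13-HDHEA, 0.0161 for 16-HDHEA and -0.111 for the combination, the last with -0.0664, -0.18 and -0.0864 in the 3 experiments.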

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

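The comparison of 13-HDHEA with the combined treatment and the 3 tests of what lies behind the Mnd1 difference were chosen after that difference was seen, while the comparison of the isomers and the splits of the arrays were planned.

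Mnd1 stood out because the effects of the isomers on it differed when the difference itself was tested: the effect of 13-HDHEA minus that of 16-HDHEA was -1.105 on the log2 scale (SE 0.127, 95% interval -1.38 to -0.83, lower in 3 of 3 experiments). With 13-HDHEA the probe set lay below the 40th percentile of 3 of 3 arrays, so this size is only that measured, and against the percentile the difference was at least 0.82. Its limma adjusted p was 0.0102, and 0.00381 to 0.241 over the alternatives. Against vehicle, 13-HDHEA gave -1.35 (adjusted p = 0.00091, and 0.000426 to 0.105 over the alternatives). 13-HDHEA at 5.0 µM also gave lower Mnd1 than 2.5 µM of each compound together (log2 difference -1.14 as measured, SE 0.127, and at least 0.86 against the percentile, adjusted p = 0.00691), the 1 gene that passed in that comparison.

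A single array of the 13-HDHEA and vehicle groups was argued against, since the highest adjusted p of the difference from vehicle with 1 of these arrays left out was 0.0116. Noise of dim probe sets was not settled. Of 2535 other genes within 0.5 log2 of its mean brightness over all arrays, 0 changed by as much with 13-HDHEA. The largest change among them was 0.843, below the 1.07 that Mnd1 kept against the percentile. The values of Mnd1 spanned at most 0.37 within a group. Both largely restate how Mnd1 was picked, as the 1 gene of 15468 that passed on these arrays. Its 13-HDHEA values also lay below the brightness at which the other genes were matched. Fewer dividing cells were argued against by the cell cycle list, whose median change with 13-HDHEA was -0.0172 (quartiles -0.0549 to 0.045 over 31 genes). The bound set for this explanation, after the values were seen, was a fall to -0.998. It is 0.5 of the measured Mnd1 change, scaled by the LPS changes of the list and of Mnd1. It assumes that fewer dividing cells would move both as LPS did. Hybridization of another transcript to this single probe set, a sequence difference under its probes and a handling difference shared by the 13-HDHEA arrays were not tested, so that an effect of 13-HDHEA on Mnd1 stays a hypothesis, found and tested on the same arrays.

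Splits of the 6 arrays of each pair of groups bear on these counts. For 13-HDHEA against vehicle the real split gave 1 gene and the highest other split 0, and for 13-HDHEA against 16-HDHEA the real split also gave 1 and the highest other 0. In each, 1 of 10 splits gave a count as large, and 10 splits are too few for a share under 0.05. Among the 4 splits that part every experiment, with experiment as a block, the real split gave 1 gene and the highest other 0 in both comparisons.

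Probe sets that name no single gene carried signal outside the comparisons reported. Of 9889 tested probe sets that the platform's gene table did not list, 291 changed with LPS against cells without it, 140 higher and 151 lower. Of 1239 tested probe sets with several gene symbols, 301 changed, 130 higher and 171 lower.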

How the results depend on the processing

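The correlations between different experiments, the exact permutation and the comparison of 13-HDHEA with the combined treatment were chosen after the data were seen, and the other settings were planned.

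Of the named genes' results, none changed direction while called, and those that changed side of the threshold were 6 that gained and 17 that lost a call with LPS, 1 that lost it with 13-HDHEA and 5 between the isomers, given beside the result where a block or an array left out did it, the rest coming with array weights, repeated normalization, no filter or smaller fits for Il10, Fap, Pdgfra and Cdh5. List results that kept their side of the threshold were 450 with LPS, 455 with 13-HDHEA, 467 with 16-HDHEA and 462 with the combination. They were 469 between the isomers, 549 against the mean of the singles and 627 over any HDHEA. These counts include results that passed in neither fit, whatever their direction. With 13-HDHEA, for example, the cell cycle list was down in camera, and up with experiment as a block. The reversed one was the list cell cycle and DNA replication, 13-HDHEA minus 16-HDHEA, with an unadjusted p of 0.00338 without 16-HDHEA replicate 1. Over the arrays left out its p ran from 0.00273 to 0.488.

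Leaving out 1 array gave 3951 to 4203 genes and 12 to 14 lists with LPS. It gave 1 to 2 genes (2 without vehicle replicate 1) and 0 to 3 lists with 13-HDHEA, no gene and 0 to 2 lists with 16-HDHEA, and no gene and 0 to 3 lists with the combination. Between the isomers it gave 0 to 1 genes and 0 to 2 lists, against the mean of the singles no gene and 0 to 1 lists, and over any HDHEA no gene and 0 to 2 lists. A group left with fewer arrays borrows its spread from the others.

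With experiment as a block, 16-HDHEA shifted 1 list, the isomers differed in 1, the combination differed from the mean of the singles in 1 and any HDHEA shifted 2. With the block and an estimated correlation, or with the block and fry, each of these counts was 0. The block gave 5313 genes with LPS, 4591 of them shared, and beyond these lists, Il10 and Fap changed no call of a list or named gene. With array weights the counts of lists were 3 for the combination, 1 against the mean of the singles and 2 for any HDHEA. Trend and robust settings gave 3 lists for any HDHEA, and the 60th percentile filter gave 1 for 13-HDHEA and 2 for any HDHEA. The stress response list also passed for 13-HDHEA with trend and robust settings (adjusted p = 0.0176) and with array weights (0.0394), in a range of 0.01 to 0.934 over its alternatives. With LPS, the list fatty acid synthesis and desaturation passed with trend and robust settings (0.0429, range 0.00047 to 0.273), and mitochondrial respiration and TCA cycle passed with no filter on dim genes (0.0387, range 0.000249 to 0.3). With only the groups compared in the fit, 0 genes passed for 13-HDHEA and 0 between the isomers, where the residual degrees of freedom fell from 10 to 4. Camera with an estimated correlation gave 8 lists with LPS, and fry gave 20. Both gave 0 for 13-HDHEA, for the combination and for any HDHEA. The exact permutation gave 0 for any HDHEA as well, which decides nothing. With 64 arrangements, a list could pass after adjustment only if many reached the smallest p together. With LPS, 2245 genes also changed at least 1.5-fold. At an unadjusted p under 0.01 the counts were 120 for 13-HDHEA, 74 for 16-HDHEA, 92 for the combination, 95 between the isomers, 98 against the mean of the singles and 102 for any HDHEA. The cross-fitted correlations with the LPS effect were -0.0498, 0.0161 and -0.111, and the correlations of effects from different experiments 0.0229, 0.0205 and 0.000146. The cause of these changes was not tested. Signal near background limits dim genes such as Mnd1 with 13-HDHEA.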

Other observations

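The 9 of 9 comparisons within experiments, the exact permutation, how both tests of the interferon-stimulated genes were read and the test of PPAR targets were chosen after the values were seen, while the splits and the interferon tests themselves were planned.

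A lipid droplet gene ran higher with HDHEA in every experiment without passing. Plin2, whose product coats lipid droplets, exceeded the vehicle array of its own experiment in 9 of 9 arrays with an HDHEA, by 0.18 to 0.40 on the log2 scale. Its mean difference was 0.30 (SE 0.109, adjusted p = 1 in limma, and 0.625 with experiment as a block), and it was picked out of 601 genes with 1 sign in all 9 comparisons, 270 higher and 331 lower. Simulated unchanged groups gave 466.7 such genes on average and 6 to 1366 over 100 draws. Besides the interferon-stimulated genes, a few lists also kept 1 sign in 9 of 9 arrays: eicosanoid enzymes (0.0604) and neutrophil markers (0.117) were higher, and stress response genes (-0.0556) lower. In the exact permutation, which a few lists alone could not pass after adjustment, their adjusted p was 0.146, 0.146 and 0.292. Of the neutrophil markers, Mpo (2.88), Ly6g (2.99) and Ltf (3.05) had vehicle means below their arrays' 40th percentile. Cxcr2 (3.35) and Mmp8 (4.23) lay above it. How far the rise of this list reflects detected transcripts was not resolved.

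Because fatty acid derivatives can activate PPAR receptors, Plin2 and Cpt1a may reflect induction of PPAR targets. The list of 21 targets was higher than vehicle in 7 of 9 arrays, with an exact permutation p of 0.125 (adjusted p = 0.389), and its members' quartiles were -0.05 to 0.0815. This leaves PPAR target induction open.

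The interferon-stimulated genes were lower with HDHEA in 9 of 9 arrays, by a list mean of -0.137 (camera adjusted p = 0.000398, and 1.69e-07 to 0.773 over the alternatives). Against vehicle the range was 6.29e-06 to 0.934 for 13-HDHEA, 0.000885 to 0.963 for 16-HDHEA and 1.54e-08 to 0.992 for the combination. A weaker LPS response of all induced genes stays open. The 31 of these genes that LPS raised had a median of -0.113, which 0 percent of 10000 random lists matched for LPS response reached (median -0.0176, central 95% -0.0625 to 0.0173). By the bound set beforehand this would have excluded it, but random lists ignore that interferon-stimulated genes vary together, and the mean of the list shifted with an SD of 0.0518 in draws of unchanged groups, so the gap is under 2 such SDs. Array-to-array variation shared by these genes stays open too. The mean of the list moved as far in 0 of 100 draws of unchanged groups (0.131 at most), which by the bound set beforehand would have excluded it, but camera called the list in 30 of those draws, the draws are simulated, and the list was the one of 28 that stood out. Both readings replaced the bounds after the values were seen. A lower interferon response with HDHEA may therefore be proposed only as a hypothesis, and the vehicle arrays, shared by all 3 comparisons, could carry part of it.

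Splits of the arrays into groups of the same sizes bear on the other counts. LPS against no LPS gave 4616 genes where the highest other split gave 0, and 13 lists where the highest other gave 11, and in each 1 of 10 splits was as large. For the lists, 4 of 10 splits were as large as the real 2 with 13-HDHEA (highest other 6) and 7 of 10 as large as the real 1 with the combination (5). In all of these, 10 splits are too few for a share under 0.05. Where the real count was 0, every split reaches it (10 of 10), which tests nothing: other splits gave up to 4 lists for 16-HDHEA, 3 lists between the isomers, and 1 gene each for 16-HDHEA and for the combination. Among the 4 splits that part every experiment, with experiment as a block, LPS gave 5313 genes (highest other 0) and 13 lists (11), 13-HDHEA 2 lists (2), 16-HDHEA 1 list (1), the combination 1 list (2) and the isomers 1 list (1).

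For any HDHEA against vehicle, 69 of 100 drawn splits shifted as many lists as the real 1, with up to 6, so that chance was not excluded for this count. The counts of 0 genes there and of 0 genes and 0 lists for the combination against the mean of the singles are reached by every split (100 of 100 drawn and 84 of 84), which tests nothing. Other splits gave up to 18 genes in the former, and up to 81 genes and 5 lists in the latter. The 81 genes came from setting the 3 arrays of experiment 1 against the rest, and the 18 from 3 LPS arrays of experiment 1, so that these arrays are structured by experiment. With experiment as a block, the 27 splits that part the experiments of the combination against the singles gave at most 1 gene and 3 lists (real 0 and 1), and the 28 of any HDHEA gave at most 1 gene and 2 lists (real 0 and 2).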
